A study of Solanum lycopersicum with 12 samples.

How the data were processed

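RNA was measured on 12 Affymetrix tomato arrays, 3 for each of 4 groups of Micro-Tom, a dwarf tomato cultivar. The groups were seeds sampled on day 1 and seedlings sampled on day 11, each grown on regular Murashige and Skoog agar medium or on the same medium with helical multi-walled carbon nanotubes (MWCNT, hollow carbon tubes of coiled shape) at 25 µg/ml. Per the labels, total RNA was isolated with a plant RNA mini kit and amplified to biotin-labelled cRNA before hybridisation. The 6 arrays of regular medium are labelled as re-used from other work. The labels do not say that the replicates of a group are separate plants or cultures, so p-values measure the spread between these samples, which may be technical.

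The deposited values are linear intensity values, 1 per probe set, made in GCOS per the submitters' processing notes, which give no version. The summary algorithm and the background correction are not given in the sources used here, and no detection calls were used here. After leaving out the top and bottom 2% of probe sets, the mean of each array lay between 500.06 and 500.12, so every array had been scaled to a common target before deposit. The values ran from 0.0203 to 19366, and 0 of them were at or below 0. No pair of arrays held identical values. Very low values carry little signal over background, and a difference between them is given on the log2 scale after adding 16, which understates the change of dim probe sets.

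Of the 10209 probe sets, 108 array controls were left out of the tests, which leaves 10101. Gene symbols came from the platform annotation of 2007. It gives 1 symbol for 909 of the tested probe sets (9.00%), several for 0 and none for 9192. These are 802 distinct symbols, of which 176 are LOC numbers. The gene IDs of 885 probe sets were found in a reference gene table of assembly SLM_r2.1 and those of 24 were not. The table was used for names only, and no coordinates are given because the build behind the array design is not given in the sources used here. Probe sets without a symbol are described by their values.

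The comparisons, tests, gene lists, most of the alternatives and the rule for named genes were fixed before the data were examined. The 5 comparisons were helical MWCNT against regular medium in seeds, the same in seedlings, the difference between those effects, and seedlings against seeds on each medium. A linear model with 1 mean per group was fitted in limma 3.58.1 (R 4.3.3) to log2(value + 16) of all 12 arrays, with no further normalization. Variances were moderated with an intensity trend, on 8 residual and 6.52 prior degrees of freedom at the first probe set. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 10101 probe sets within a comparison, with a threshold of 0.05. Different probe sets of one gene were kept apart. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3 in python 3.11.15, and exact permutation tests were run in R 4.3.3.

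Genes were named by a fixed rule. Per comparison, it took the 10 largest rises and 10 largest falls among probe sets that passed the threshold, carried 1 symbol and had groups that did not overlap, with 1 probe set per gene. For seedlings against seeds it took 5 per direction. Where none passed in a direction, it took the 5 with the lowest unadjusted p. It added up to 3 members of each gene list with the lowest p and at most 2 rises and 2 falls without a gene name. Other members are named where they were chosen after their values were seen, and this is said there.

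Of 21 gene lists fixed in advance, 17 had at least 3 probe sets and were tested with camera in limma at a preset correlation of 0.01, adjusted over the 17 lists. The other 4 (seed storage and late embryogenesis proteins, trichome and terpenoid synthesis, epidermal lipids, housekeeping reference) had fewer and were not tested. Another 20 lists were put together after the gene symbols were seen and before any fold change was computed. Camera with a correlation estimated from the data and fry were the alternatives.

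The model was first tested on simulated data with 50 probe sets changed at each size. Before the change each probe set had the same mean in all groups, independent noise and 1 spread pooled over the groups. The simulation left out any spread particular to a stage and any structure shared by arrays, so its shares need not hold for these seeds or seedlings. In seedlings it recovered 34%, 84%, 98% and 100% of changes of 0.5, 1, 2 and 3 on the log2 scale, with 13 false calls. In seeds it recovered 42%, 80%, 98% and 100%, with 4 false calls. For the difference between stages the shares were 10%, 54%, 96% and 100%, with 8 false calls. The stage comparison recovered 36%, 86%, 100% and 100% on regular medium with 8 false calls, and 28%, 82%, 98% and 100% on helical MWCNT medium with 5. In a list test on simulated seedlings, camera called a list of 10 members shifted by 0.5 in 100% of 20 repeats, and it called 1 of 380 unshifted lists. Those lists were random probe sets with independent noise, so these rates need not hold for lists of genes that vary together.

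Alternatives to the model were quantile normalization over all arrays or within a stage, median centring, pseudocounts of 1 and 64, leaving out the dimmest 40% of probe sets, variances without a trend or estimated robustly, a fit of only the groups compared, array weights, the replicate number as a block, a fold filter of 1 on the log2 scale, the mean of probe sets per gene, and leaving out each array in turn. The number of arrays limits the precision of every value.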

Results

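The arrays measured transcript levels in Micro-Tom tomato at a germinating stage (seeds, day 1) and at a young plant stage (seedlings, day 11), with 3 arrays per stage and medium. Seeds and seedlings grew on regular agar medium or on medium with 25 µg/ml helical MWCNT, and the comparisons ask which transcripts differ between the media at each stage. The median intensity of an array was 107 to 128 in seeds and 162 to 185 in seedlings. Arrays of one group correlated at r = 0.980 to 0.994 over probe sets, arrays of different media at 0.979 to 0.992 in seeds and 0.984 to 0.989 in seedlings, and arrays of different stages at 0.718 to 0.739. Probe sets are not independent replicates, so these coefficients only describe the arrays.

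The free-text descriptions of 4 helical MWCNT arrays differed from their other labels. Seed arrays 2 and 3 were described as seedlings of 11 days, yet they correlated with the other seed arrays as above. Seedling arrays 1 and 2 were described as 20 days old, while array 3 was described as 11 days old. The median intensity was 163 and 162 on arrays 1 and 2 and 183 on array 3, against 182 to 185 on the seedling arrays of regular medium. The groups follow the other labels. The 6 re-used arrays are the 6 arrays of regular medium, and the array identifiers ran in 1 unbroken sequence over both media within each stage, regular medium first. Medium, re-use and place in the sequence therefore cannot be told apart, and neither can stage and sequence. The signal ratio of 3' to 5' probes for elongation factor 1-alpha, which grows as RNA breaks down, was 5.86 to 33.6 in seeds and 2.44 to 5.36 in seedlings.

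In seedlings, genes of flavonoid synthesis were lower on helical MWCNT medium. CHS1 and CHS2, chalcone synthases that make the first flavonoid intermediate, fell from 307 ± 5.19 to 91.3 ± 14.2 and from 1174 ± 190 to 573 ± 47.2 (mean intensity ± SD, n = 3). DFR, dihydroflavonol reductase on the way to anthocyanins, fell from 287 ± 11.7 to 88.3 ± 15.1. The log2 differences were -1.60 for CHS1 (SE 0.17, adjusted p = 5.25e-05), -1.0 for CHS2 (SE 0.11, adjusted p = 0.000123) and -1.55 for DFR (SE 0.19, adjusted p = 0.000307). These are all 3 probe sets of the phenylpropanoid and flavonoid synthesis list, and all 3 also fell when adjusted over the list alone. The list moved down against the other probe sets (camera adjusted p = 2.91e-09, and adjusted p = 0.0134 with an estimated correlation). With a pseudocount of 1 the adjusted p of DFR was 0.415, within a range of 2.23e-06 to 0.415 over its alternatives.

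**Figure D1:**
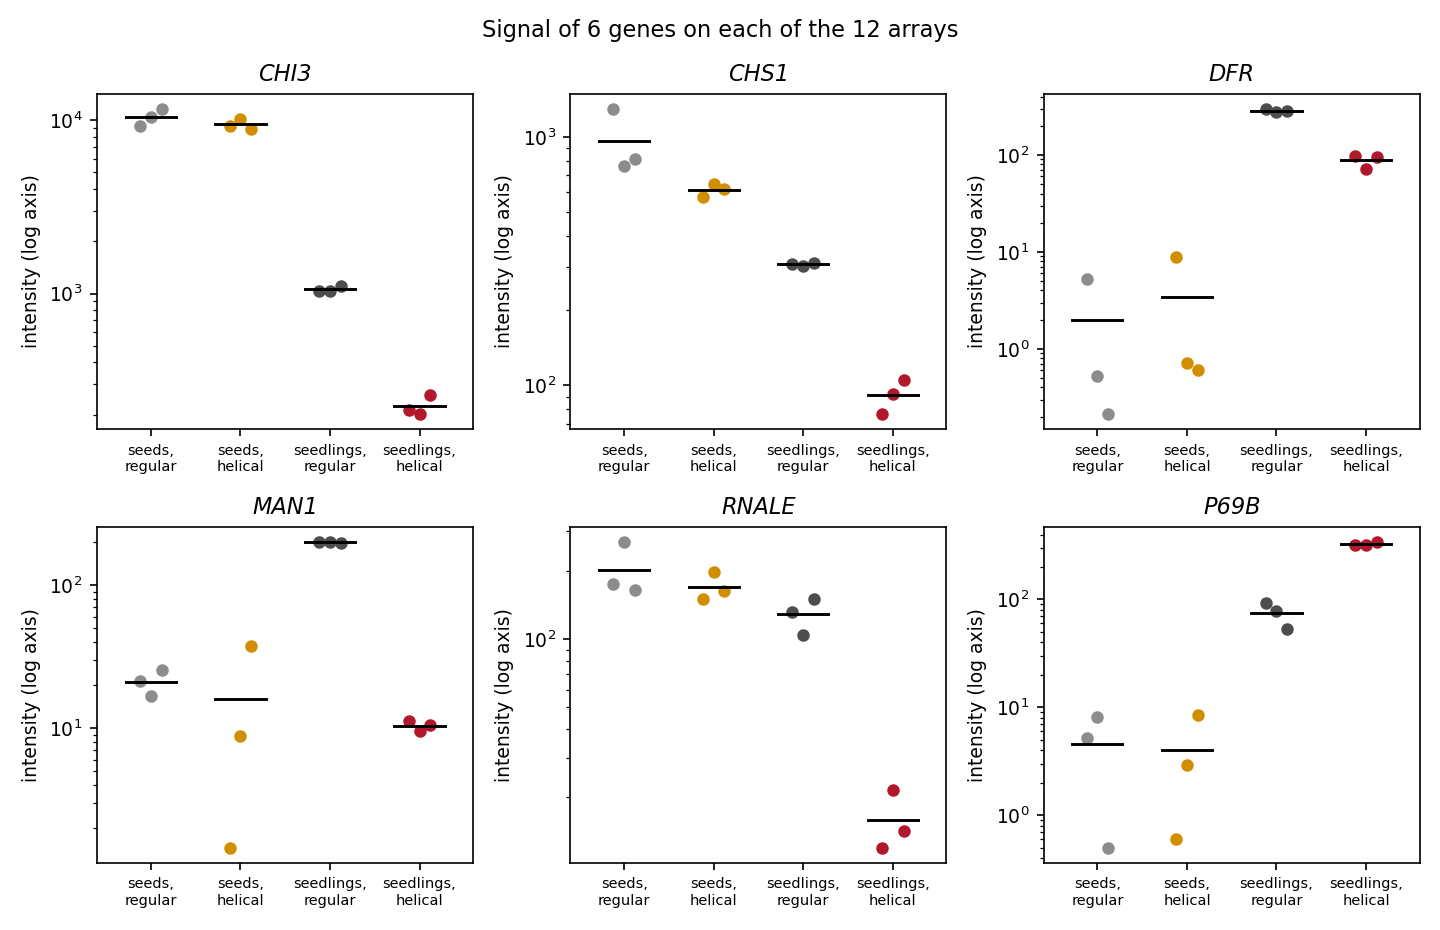
Intensity of CHI3, CHS1, DFR, MAN1, RNALE and P69B on a log axis, with 1 point per array of the 4 groups and black bars at the group means. MAN1, CHI3 and CHS1 lie lower on all 3 helical MWCNT seedling arrays than on all 3 seedling arrays of regular medium, and P69B lies higher.

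Endo-beta-mannanases, which break down mannans of the endosperm wall during and after germination, were also lower in helical MWCNT seedlings. MAN1 fell from 200.03 ± 0.595 to 10.4 ± 0.788 (log2 difference -3.03, SE 0.29, adjusted p = 2.18e-05, n = 3). MAN2 fell from 31.7 ± 4.03 to 4.58 ± 4.15 (-1.23, SE 0.17, adjusted p = 0.000994), although with a pseudocount of 64 its adjusted p was 0.0731, in a range of 2.41e-05 to 0.173. Man4, the last of 3 members of the reserve mobilisation list, was near the floor at 0.571 and 2.08. The list moved down, with 2 members down and also 2 when adjusted over the list alone (camera adjusted p = 0.00106, and adjusted p = 0.0432 with an estimated correlation). The dehydrin TAS14, a late embryogenesis protein of the untested list of 2, fell from 195 ± 30.1 to 85.0 ± 6.01 (-1.06, SE 0.22, adjusted p = 0.0268). The other member, LEA14, differed by -0.34 (adjusted p = 0.270). Adjusted over the list alone, both were lower. The call for TAS14 was lost with median centring (adjusted p = 0.103, in a range of 0.000493 to 0.520).

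Defence genes moved in both directions in seedlings. CHI3, an endochitinase, fell from 1058 ± 41.7 to 225 ± 30.9 (log2 difference -2.17, SE 0.11, adjusted p = 1.08e-08, n = 3), and the chitinase CHI9 fell from 3252 ± 167 to 2405 ± 143 (-0.43, SE 0.09, adjusted p = 0.0332). P69B, a subtilisin-like protease of the pathogenesis-related class, rose from 74.7 ± 20.3 to 327 ± 10.9 (1.94, SE 0.21, adjusted p = 7.14e-05). Of 9 probe sets on the pathogenesis-related list 1 rose and 2 fell, and 2 rose and 2 fell when adjusted over the list alone, the second rise being CHI17 (0.40), chosen after its value was seen (camera adjusted p = 0.854). Its median of -0.06 and mean of -0.02 lay below 0 while the test pointed up. PR-P2, a pathogenesis-related protein outside that list, fell from 283 ± 41.5 to 90.1 ± 5.61 (-1.49, SE 0.19, adjusted p = 0.000433). With median centring the call for CHI9 was lost (adjusted p = 0.331, in a range of 0.00151 to 0.753). With a pseudocount of 1 that for P69B was lost (0.238, in a range of adjusted p from 9.76e-07 to 0.238).

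Among wound and jasmonate genes, the lipoxygenase TomloxE fell from 318 ± 51.5 to 117 ± 5.28 (log2 difference -1.31, SE 0.15, adjusted p = 9.81e-05, n = 3). CEVI57 fell from 92.9 ± 18.3 to 22.2 ± 3.47 (-1.50, SE 0.19, adjusted p = 0.000337). LOX1.1, another lipoxygenase, was at 685 ± 95.8 and 387 ± 23.2 (-0.79, adjusted p = 0.0787). In all, 2 of the 16 probe sets of that list fell, and when adjusted over the list alone 1 rose (loxC, 0.57) and 5 fell, with AOS (-0.72), loxD (-0.55) and LOX1.1 besides those 2. AOS, loxC and loxD were chosen after their values were seen. The list did not stand apart from other probe sets (camera adjusted p = 0.166), while fry, which asks whether the members move one way on balance, gave an adjusted p of 0.00465.

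The antioxidant and cell wall lists also held changes in both directions or in a few members. SODCP.2, a chloroplast copper/zinc superoxide dismutase, rose from 1632 ± 182 to 2464 ± 162 (log2 difference 0.59, SE 0.10, adjusted p = 0.00368, n = 3). APX, an ascorbate peroxidase, fell from 487 ± 74.4 to 244 ± 34.1 (-0.95, SE 0.18, adjusted p = 0.0141). Of 14 antioxidant probe sets 1 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.721). Their median and mean were both -0.06 while the test pointed up. Of 41 cell wall probe sets 4 fell, and 1 rose (EXPA4, 0.30) and 4 fell when adjusted over the list alone (camera adjusted p = 0.519). The falls were MAN1, MAN2, XTH3 (-0.95), a xyloglucan endotransglucosylase/hydrolase chosen after its value was seen, and Cel1, an endoglucanase that fell from 106 ± 19.0 to 20.5 ± 2.26 (-1.73, SE 0.19, adjusted p = 9.81e-05). The median of that list was 0.09, its mean -0.14, and its test pointed up. RNALE, a ribonuclease known to be induced by phosphate starvation, fell from 129 ± 22.7 to 15.97 ± 5.02 (-2.18, SE 0.20, adjusted p = 1.46e-05). With a pseudocount of 1 the adjusted p of Cel1 was 0.213 and that of APX was 0.108, in ranges of 4.81e-06 to 0.213 and 0.00179 to 0.831.

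The list of ethylene synthesis and response genes moved up in seedlings, by small amounts. ERF3, an ethylene response factor, rose from 87.5 ± 1.34 to 135 ± 12.9 (log2 difference 0.54, SE 0.13, adjusted p = 0.0488, n = 3), and it was the 1 of 32 probe sets that passed. Its other probe set differed by 0.09, and the mean of both had an adjusted p of 0.466, in a range of 0.00253 to 0.979 over the alternatives. ERF4 was at 230 ± 26.6 and 353 ± 45.5 (0.59, adjusted p = 0.0590), and the ethylene receptor ETR2 at 370 ± 19.8 and 283 ± 24.6 (-0.37, adjusted p = 0.111). When adjusted over the list alone, 4 rose (ERF3, ERF4, PTI4 at 0.45 and PTI6 at 0.46) and 1 fell (ETR2), and both PTI genes were chosen after their values were seen. The list passed (camera adjusted p = 0.000737, and adjusted p = 0.0432 with an estimated correlation), at a median of 0.08 and a mean of 0.11.

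Of the metal binding and transport list, 0 of 12 probe sets passed by limma, also when adjusted over the list alone, and 1 had an unadjusted p under 0.05. Several of the 12 belong to 1 gene, the metallothionein MT4, so they are not independent. The 3 members of the list with the lowest p were at 0.31 for the metallothionein MT2 (1768 ± 193 and 2192 ± 159, n = 3), 0.22 for MTA (6081 ± 354 and 7148 ± 1113) and 0.31 for FRO1. The list as a whole lay higher (median 0.15, camera adjusted p = 0.00711), a call that was lost with an estimated correlation (adjusted p = 0.0928) and with quantile normalization (adjusted p = 0.193). Of the auxin response list, 0 of 14 passed by limma and 1 rose when adjusted over the list alone. That was IAA17, an Aux/IAA repressor, at 354 ± 30.5 and 536 ± 43.6 (0.58, adjusted p = 0.124). IAA7 differed by 0.39 and 0.32 on 2 probe sets. The list lay higher (median 0.11, camera adjusted p = 0.0171), and lost the call with an estimated correlation (adjusted p = 0.209), with the mean of probe sets per gene (0.0866) and with the 3'/5' ratio as a covariate (0.0671). With helical MWCNT array 3 alone, neither list passed (adjusted p = 0.754 for both). Without helical MWCNT array 1 the adjusted p of both lists was 0.0567. Without helical MWCNT array 2 that of the auxin response list was 0.0668, and without control array 2 it was 0.0848. For metal binding and transport the adjusted p ranged from 0.00122 to 0.754 over the alternatives, and for auxin response from 0.00453 to 0.754.

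The other lists did not pass in seedlings. The camera adjusted p was 0.0579 for aquaporins, 0.0941 for photosynthesis, 0.120 for ribosomal proteins, 0.462 for gibberellin and abscisic acid, 0.505 for root nutrient transporters, 0.505 for stress transcription factors, 0.519 for cell cycle and histones and 0.519 for heat shock proteins. Adjusted over the list alone, 1 aquaporin (pip1, 0.59) and 1 heat shock gene (HSC80, 0.30) were higher. The median and mean of the heat shock list (-0.09 and -0.02) and of the cell cycle list (-0.06 and -0.02) lay below 0 while their tests pointed up. Without helical MWCNT array 3 photosynthesis (adjusted p = 0.00453) and ribosomal proteins (0.0168) passed, and without control array 2 photosynthesis passed (0.0437). The ranges of the adjusted p over the alternatives were 0.00453 to 0.688 for photosynthesis and 0.0168 to 0.909 for ribosomal proteins. Of the untested lists, SSTLE1 of the trichome and terpenoid list was at 87.9 ± 4.78 and 148 ± 1.45 (0.66, adjusted p = 0.0830), LE16 of the epidermal lipid list at 107 ± 22.4 and 58.5 ± 13.0 (-0.72, adjusted p = 0.181), and the tubulin TUB of the housekeeping list at 2729 ± 201 and 2788 ± 9.67 (0.03).

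**Figure D2:**
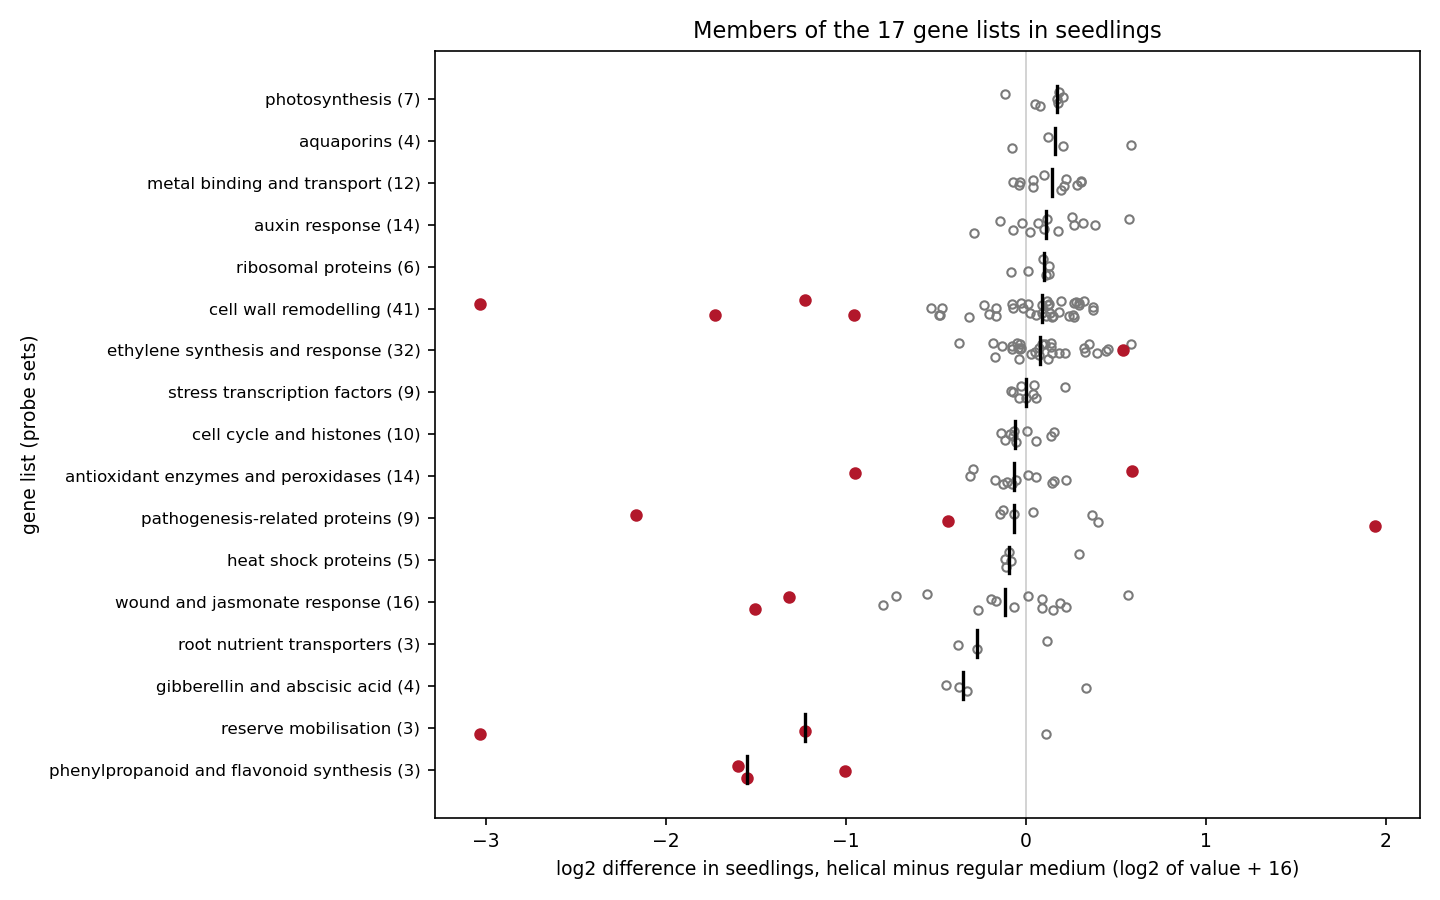
Log2 difference between helical MWCNT and regular medium in seedlings (horizontal, log2 of intensity + 16) for each member probe set of the 17 tested gene lists (vertical, ordered by median, with the number of probe sets in brackets). Each point is 1 probe set, filled red where it passed the threshold and open grey where it did not, and the black bars are list medians, lowest for phenylpropanoid and flavonoid synthesis (-1.55) and reserve mobilisation (-1.23).

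Over all genes, 133 of 10101 probe sets passed in seedlings, 41 higher and 92 lower on helical MWCNT medium, and 1203 had an unadjusted p under 0.05. All 133 had groups that did not overlap, as did 2242 probe sets in all (22.2%, where chance gives 10%). Of the 133, 59 differed by at least 1 on the log2 scale, 13 higher and 46 lower. Named genes made up 39 of the calls, 7 higher and 32 lower. The other rises by the rule were LOC543986 (1.07, but with an adjusted p of 0.557 at a pseudocount of 1, in a range of 0.00270 to 0.557), h52 (0.59), LOC543878 (0.59) and LOC544187 (0.56), and the other fall was LOC543899 (-1.92, from 334 ± 10.5 to 76.4 ± 7.03). Among probe sets without a gene name, the largest rises were 2.85 (301 ± 75.6 to 2248 ± 419) and 1.69 (47.9 ± 11.3 to 188 ± 11.4). The largest falls were -4.84 (1139 ± 61.4 to 25.9 ± 13.8) and -4.48 (482 ± 10.7 to 6.33 ± 2.51). Rises made up 30.8% of the calls, against 42.5% with quantile normalization over all arrays, 43.2% within a stage and 44.2% with median centring.

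With helical MWCNT array 3 alone 36 probe sets passed in seedlings, and 14 of the 26 named genes and probe sets with a call lost it, at an adjusted p of 0.0541 to 0.979. They were LOC543986, SODCP.2, h52, LOC543878, LOC544187, ERF3, DFR, CEVI57, PR-P2, APX, MAN2, CHI9, TAS14 and the unnamed rise of 1.69. Over all alternatives the adjusted p of these 14 lay between 1.96e-06 and 0.979. Leaving out 1 array changed how many probe sets passed. The count was 83 without control array 1, 82 without control array 2, 74 without helical MWCNT array 1 and 84 without helical MWCNT array 2. Of the genes given here, CHI9 and TAS14 lost the call without helical MWCNT array 3 (adjusted p = 0.0554 and 0.0810). ERF3, CHI9, h52, LOC544187 and APX lost it without control array 2, at an adjusted p of 0.0928 to 0.170. Without control array 1, LOC543986, h52, LOC543878, LOC544187, ERF3, CHI9 and TAS14 did, at an adjusted p of 0.0965 to 0.167. Without control array 3, the same genes with APX in place of LOC544187 did, at an adjusted p of 0.0555 to 0.139. Without helical MWCNT array 1, h52, LOC543878, LOC544187, ERF3, APX, CHI9 and TAS14 did, at 0.0663 to 0.246, and without helical MWCNT array 2 all 8 of these genes did, at an adjusted p of 0.0926 to 0.202.

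**Figure D3:**
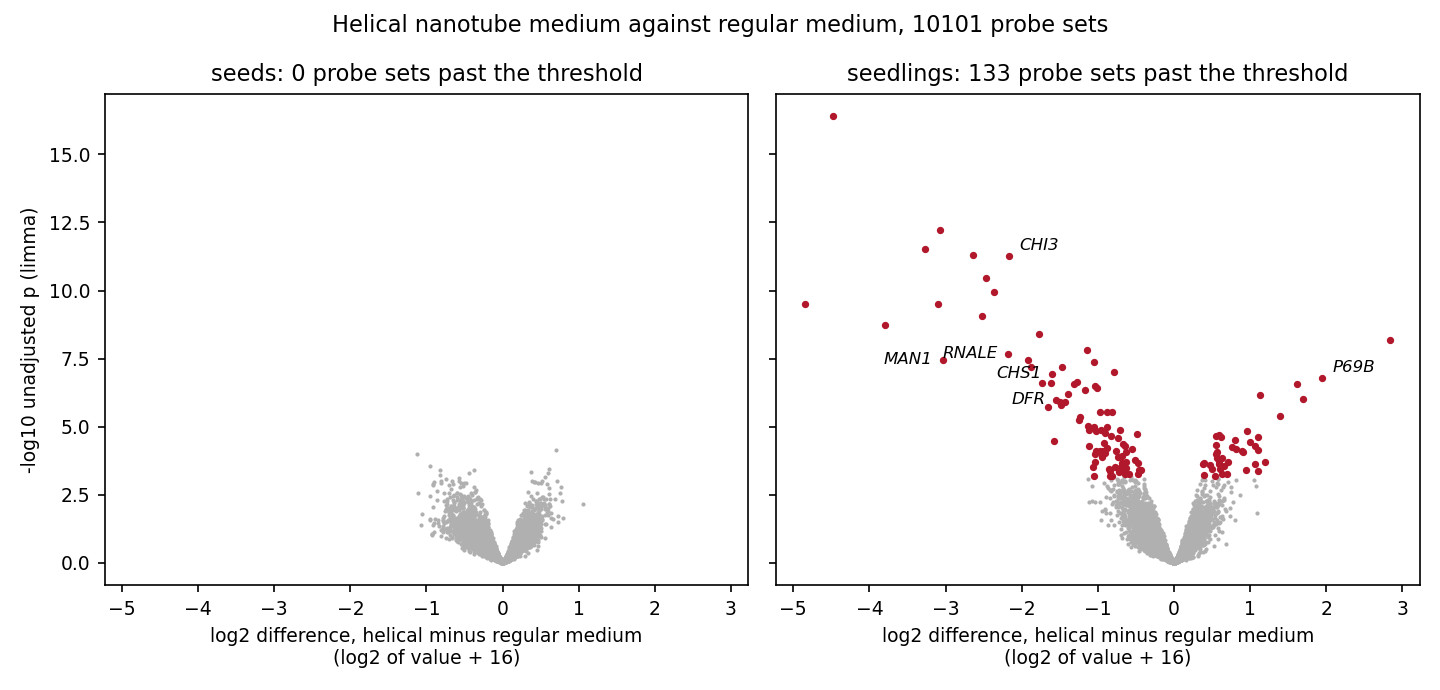
Log2 difference of helical MWCNT over regular medium (horizontal) against -log10 of the unadjusted limma p (vertical) for the 10101 tested probe sets, in seeds and in seedlings. In seedlings the 133 probe sets past the threshold are marked, 41 higher and 92 lower, and in seeds 0 are.

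In seeds on day 1, no gene passed between the media. By limma 0 of 10101 probe sets passed, 747 had an unadjusted p under 0.05 and the lowest adjusted p was 0.423. The groups did not overlap for 890 probe sets (8.81%, where chance gives 10%). CHS1, the chalcone synthase that fell in seedlings, was at 961 ± 294 on regular and 612 ± 38.0 on helical MWCNT medium (log2 difference -0.60, SE 0.17, adjusted p = 0.538, n = 3). FDH, a formate dehydrogenase, was at 1141 ± 200 and 815 ± 165 (-0.48, adjusted p = 0.538), and the metallothionein MT4 at 1921 ± 1060.4 and 3017 ± 45.0 on 1 of its probe sets (0.78, adjusted p = 0.541), while its other 3 probe sets were at -0.01, 0.13 and -0.05. ProT2, TAPG2, PG2 and LOC544075 differed by 0.68, 0.49, 0.46 and 0.47, and ACS3, EXP5 and sbt3 by -0.73, -0.55 and -0.60. These 7 were dim in seeds, with group means of 0.584 to 24.0, and none passed.

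No gene list passed in seeds either, with adjusted p from 0.201 to 0.984 over the 17 lists, and 3 had an unadjusted camera p under 0.05. Auxin response pointed up (unadjusted p = 0.0118, adjusted p = 0.201), with IAA17 at 0.38, IAA3 at 0.39 and IAA2 at 0.40. Heat shock proteins pointed up (unadjusted p = 0.0435, adjusted p = 0.246), with HSP17.4 at 0.45, HSP17-6 at 0.32 and HSP21 at 0.31. HSP17-6 was at -0.04 with the 3'/5' ratio as a covariate, and HSP21 at -0.06 with array weights. Phenylpropanoid and flavonoid synthesis pointed down (unadjusted p = 0.0311, adjusted p = 0.246), with CHS2 at -0.22 and DFR at 0.09. When adjusted over the list alone, 1 of its 3 probe sets, CHS1, was lower. Without control array 3, 2 probe sets passed in seeds, of which the same 1 of 4 MT4 probe sets was 1 (1.20, adjusted p = 0.000102, in a range of 0.000102 to 1), and without helical MWCNT array 1, 3 passed. Without control array 2, the auxin response and heat shock lists passed (adjusted p = 0.0293 for both, with highest values of 0.908 and 0.950 over the alternatives). A pseudocount of 1 gave 5 calls, of which only rnalx, a ribonuclease, carries a name (2.06) and was chosen after its value was seen. Array weights gave 5 calls, and these 5 and the 3 without helical MWCNT array 1 carry no gene name.

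The difference between the effects of helical MWCNT in seedlings and in seeds was tested directly, on the same seedling arrays as above, so it is not independent of the seedling result. MAN1 (log2 difference of differences -2.66, SE 0.41, adjusted p = 0.00517), CHI3 (-2.02, SE 0.15, adjusted p = 3.24e-06) and RNALE (-1.97, SE 0.28, adjusted p = 0.00308) differed between the stages toward a lower level in seedlings. In seeds CHI3 was at 10453 ± 1219 and 9452 ± 600.2 on regular and helical MWCNT medium, and RNALE at 203 ± 56.7 and 171 ± 25.4 (n = 3). MAN1 was dim in seeds, at 21.2 ± 4.38 and 15.9 ± 19.0, which leaves little room for a fall there. P69B, with a group mean of at most 4.61 in seeds, went the other way (1.99, SE 0.29, adjusted p = 0.00391). LOC543899 (-1.86), Cel1 (-1.72), PR-P2 (-1.64), DFR (-1.64), MAN2 (-1.56), TomloxE (-1.23), CEVI57 (-1.30), APX (-1.25) and CHS2 (-0.78) also passed, while CHS1 did not (-1.0, adjusted p = 0.0944). In seeds LOC543899 (group means of 8.03 and 6.49), Cel1 (4.80 and 4.75) and DFR (group means of at most 3.41) were at the floor, and CEVI57 (24.7 and 19.9) and APX (18.4 and 27.0) were dim. For all of these genes and MAN1 the difference rests on the seedling fall. PR-P2 (2334 and 2589) and MAN2 (1031 and 1319) were well above the floor in seeds. Among probe sets without a gene name, the largest differences were 2.81 and 1.68 on the higher side and -5.31 and -4.39 on the lower. Of these 4, the first and both of the lower ones are the largest rise and falls given for seedlings.

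In all, 57 probe sets passed for this difference, 10 higher and 47 lower, and 886 had an unadjusted p under 0.05. Of the 57, 53 were also called in seedlings, all 53 in the same direction. Phenylpropanoid and flavonoid synthesis pointed down for this difference (2 of 3 down, 3 down when adjusted over the list alone, camera adjusted p = 3.05e-06, and adjusted p = 0.0458 with an estimated correlation). Reserve mobilisation did too (2 of 3 down, also over the list alone, camera adjusted p = 0.00452), a call lost with an estimated correlation (adjusted p = 0.0933). DFR of the former list and MAN1 of the latter were at the floor or dim in seeds, so for them the difference rests on the seedling fall. Ethylene synthesis and response pointed up (PTI4 0.65, ERF3 0.55 and PTI6 0.55, 0 of 32 past by limma and 0 when adjusted over the list alone, camera adjusted p = 0.0342), and lost the call with an estimated correlation (adjusted p = 0.217). The other 14 lists did not pass, with adjusted p from 0.244 to 0.883. CEVI57 lost the call on leaving out any array other than seed helical MWCNT array 1, APX any other than seed helical MWCNT array 2, and CHS2 any other than seed control array 1 and seedling control array 2, at an adjusted p of 0.0501 to 0.171. Over the alternatives, the adjusted p ranged from 0.0118 to 0.505 for CEVI57, from 0.0118 to 0.666 for APX and from 0.00704 to 0.385 for CHS2. With a pseudocount of 1 the call was also lost for MAN1 (adjusted p = 0.374), P69B (0.537), LOC543899 (0.313), Cel1 (0.582), DFR (0.601) and the second unnamed rise (0.589), each the highest over its alternatives, against lowest values of 1.66e-05 to 0.000364. MAN2 lost it with a pseudocount of 64 (adjusted p = 0.0633, in a range of 0.000690 to 0.146). With helical MWCNT seedling array 3 alone 12 of the 17 named calls were lost, at an adjusted p of 0.0593 to 0.666, namely MAN1, P69B, LOC543899, Cel1, PR-P2, DFR, MAN2, TomloxE, CEVI57, APX, CHS2 and the first unnamed rise. With helical MWCNT seed array 1 alone 9 did, at 0.0533 to 0.283, namely RNALE, LOC543899, PR-P2, MAN2, TomloxE, CEVI57, APX, CHS2 and the second unnamed rise. Over all alternatives the adjusted p of these genes lay between 1.66e-05 and 0.666. CHI3 and both unnamed falls kept the call under every alternative run. CHS1 passed without seed control array 1 (adjusted p = 0.00225, in a range of 0.00173 to 0.773).

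Between seeds and seedlings on regular medium, genes of the photosynthetic apparatus were among the largest rises. PSBO and PsbQ, proteins of the oxygen-evolving complex, rose from 15.98 ± 2.84 to 9159 ± 331 and from 10.3 ± 2.42 to 7199 ± 419 (log2 differences 8.17 and 8.10, SE 0.12 and 0.15, adjusted p = 1.22e-16 and 1.22e-15, n = 3). The chlorophyll-binding proteins CAB6A and CAB5 rose by 7.98 and 7.95, and the metallothionein MTA by 7.96. A probe set of the carbonic anhydrase ca2 rose by 8.38, and it was chosen after its value was seen because the rule took the probe set with the lowest p. DREB1, a DREB-type transcription factor, fell from 1721 ± 85.9 to 9.89 ± 8.19 (-6.12, SE 0.19, adjusted p = 2.37e-13), and the xyloglucan endotransglycosylase XET4 from 2594 ± 435 to 49.3 ± 1.38 (-5.31). SNF4 (-5.09), TSI-1 (-5.04) and MAN2 (-4.46) fell as well. Among probe sets without a gene name, the largest rises were 9.04 and 8.76 and the largest falls -5.87 and -5.28.

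By list, 7 of 7 photosynthesis probe sets rose on regular medium, PSBR among them (7.87), with a camera adjusted p of 1.94e-05. Of 12 metal binding and transport probe sets 10 rose, such as MT2 (6.25) and FER (5.53), an iron-response regulator (camera adjusted p = 0.00193). All 6 ribosomal protein probe sets fell, for example RPS25 (-1.27), RPL8 (-1.21) and RPL37 (-1.43), with a camera adjusted p of 0.00353. Of 41 cell wall remodelling probe sets 27 rose and 7 fell, with the expansin EXP5 at 5.27 and XTH7 at 4.86 (camera adjusted p = 0.0395). Counts adjusted over the list alone were the same for these 4 lists. Each call was lost with an estimated correlation, at an adjusted p of 0.176 for metal binding and transport and 0.260 for the others. Without seedling control array 1 the cell wall list had an adjusted p of 0.0518, in a range of 1.53e-08 to 0.260. The other 13 lists had adjusted p from 0.0665 to 0.943, and by fry 16 of 17 passed. Ethylene synthesis and response had a median of -0.05, a mean of 0.62 and a test pointing down, and phenylpropanoid and flavonoid synthesis had a median of -1.56, a mean of 0.02 and a test pointing down.

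On helical MWCNT medium several of these genes were again among the largest rises. PSBO, PsbQ and MTA rose by 8.38, 8.29 and 8.15, plastocyanin (PETE) by 8.22, and 1 probe set of the carbonic anhydrase ca2 by 8.63, from 9.48 ± 3.83 to 10079 ± 1445 (SE 0.14, adjusted p = 2.57e-16, n = 3). MAN2 fell from 1319 ± 295 to 4.58 ± 4.15 (-6.02, adjusted p = 1.13e-13), as did DREB1 (-5.93), SNF4 (-5.43), XET4 (-5.32) and CHI3 (-5.30). Among probe sets without a gene name, the largest rises were 8.96 and 8.93 and the largest falls -8.95 and -8.34. Photosynthesis rose in 7 of 7 probe sets (PSBR 8.11, camera adjusted p = 1.40e-05), metal binding and transport in 10 of 12 (MT2 6.50, FER 5.30, 0.00188) and cell cycle and histones in 8 of 10 with 1 lower (CDKB2 3.00, CycA2 2.76, CycA1 3.11, 0.0361). Ribosomal proteins fell in 6 of 6 (RPS25 -1.27, RPL8 -1.02, RPL37 -1.33, 0.00775), and 26 of 41 cell wall probe sets rose and 7 fell (EXP5 6.01, 0.0361). Counts adjusted over the list alone were the same for these 5 lists. With an estimated correlation the adjusted p was 0.175 for metal binding and transport, 0.296 for photosynthesis and 0.311 for the other 3, so each call was lost. The cell cycle and histones list had an adjusted p of 0.0661 with median centring and 0.0536 with the 3'/5' covariate, in a range of 1.36e-08 to 0.311. The other 12 lists had adjusted p from 0.0768 to 0.987, and by fry 16 of 17 passed. Ethylene synthesis and response had a median of -0.13 and a mean of 0.73 with a test pointing up, and the pathogenesis-related list had a mean of 0.30 with a test pointing down.

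Over all genes, 6997 probe sets (69.3%) passed between stages on regular medium, 3922 higher and 3075 lower in seedlings, and 7102 (70.3%) on helical MWCNT medium, 3816 higher and 3286 lower. Of these, 4068 and 4115 differed by at least 1 on the log2 scale. Named genes made up 695 of the calls on regular medium (430 higher, 265 lower) and 699 on helical MWCNT medium (414 higher, 285 lower). Both comparisons share no arrays, and 6397 probe sets passed in both, 6386 of them in the same direction. Of those, 3520 were higher and 2866 lower on both, where independent lists would share 1482 and 1000.3. Both compare the same stages, so an excess over independent lists says nothing of the media. The balance of directions rested on the scaling. Rises made up 56.1% and 53.7% of the calls as deposited, 37.6% and 38.5% with quantile normalization, and 33.5% and 33.8% with median centring, which moved the median of all probe sets from 0.11 and 0.06 to -0.45 on both media. The genes named above kept their direction under each scaling. The 3'/5' ratio of elongation factor 1-alpha, given above, was higher on every seed array than on any seedling array.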

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

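The tests of plant age, of the 3'/5' ratio, of medium along the main axis of the seed arrays, of the poly-A spikes and of seed transcripts were chosen only after the results were seen, as was every value with 1 helical MWCNT array alone or with the 3'/5' ratio as a covariate.

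The effect of helical MWCNT differed between seedlings and seeds for 57 probe sets, by a test of the difference itself in limma. For most of the genes named there the difference ran toward a lower level in seedlings. The largest of these were MAN1 (log2 difference of differences -2.66), the endochitinase CHI3 (-2.02), the ribonuclease RNALE (-1.97), LOC543899 (-1.86), the endoglucanase Cel1 (-1.72), PR-P2 (-1.64), dihydroflavonol reductase DFR (-1.64), MAN2 (-1.56), CEVI57 (-1.30) and the ascorbate peroxidase APX (-1.25). TomloxE and CHS2, given above, ran the same way. The protease P69B ran the other way (1.99). In seeds MAN1 (group means of 21.2 and 15.9 on regular and helical MWCNT medium), LOC543899 (8.03 and 6.49), Cel1 (4.80 and 4.75), DFR (group means of at most 3.41), CEVI57 (24.7 and 19.9) and APX (18.4 and 27.0) were dim or at the floor. The difference for these genes rests on the seedling fall and says little about the response of seeds. Of the probe sets without a gene name, the outermost were at 2.81, 1.68, -5.31 and -4.39. With a pseudocount of 1, MAN1, P69B, LOC543899, Cel1, DFR and the rise of 1.68 lost the call, at an adjusted p of 0.313 to 0.601, against 1.66e-05 to 0.000364 at the lowest over their alternatives. CEVI57 lost the call without any array other than seed helical MWCNT array 1, and APX without any other than seed helical MWCNT array 2, at an adjusted p of 0.0501 to 0.171. Over all alternatives their adjusted p ranged from 0.0118 to 0.505 and from 0.0118 to 0.666.

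A signal outside the main measurement was that of the 4 poly-A spikes, bacterial transcripts added to the RNA. Their geometric mean was 377 ± 124 on helical MWCNT seedling arrays, above 177 ± 42.9 on control seedling arrays and 111 and 104 in seeds (SD, n = 3). Relative to the hybridisation spikes, the lowest helical MWCNT seedling array was at 0.164 and the highest control seedling array at 0.140, and the ratio of the group means was 1.69.

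The first pattern is the set of 133 probe sets called between media in seedlings, among them CHS1, CHI3 and MAN1. With the 3'/5' ratio as a covariate 133 of 133 kept the call, at a median of 0.996 times their difference. Within groups that ratio varied mostly in seeds. The SD of its mean log2 was 0.72 and 0.46 on regular and helical MWCNT medium there, against 0.04 and 0.34 in seedlings. The covariate thus rests mainly on the seed arrays and cannot decide on RNA integrity in seedlings, which stays open. Greater age of helical MWCNT arrays 1 and 2, described as 20 days old, stays open. Array 3, described as 11 days old, gave a median of 0.922 of their difference, but it is 1 array. The 133 were also called with array 3 in the group and had groups that did not overlap. That choice favours a like difference on array 3, so the ratio cannot decide on age. Re-use of the control arrays cannot be told apart from the medium, because 0 kinds of array hold both media, and an effect of the nanotubes themselves stays open as well. The poly-A spike ratio given above also separated the media in seedlings. No measure of the amounts of plant RNA and spike was available, so a difference in them cannot be told apart from the medium either.

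The 6 seedling arrays make 10 splits, too few for a share under 0.05. Only the real split gave 133, with 14 as the highest of the others. The seed arrays likewise make 10 splits, of which 10 gave at least the real 0, with 347 as the highest of the others. By limma, 747 probe sets in seeds had an unadjusted p under 0.05. Between the stages the real counts were 6997 on regular and 7102 on helical MWCNT medium. Of the 10 splits, only the real one reached each count, with 0 as the highest other by limma. These splits too are too few for a share under 0.05. For the 57 calls of the difference between stages, 5 of 100 drawn splits gave as many, so chance was not excluded, but 3 of the 4 others keep the seedling arrays split by medium and so carry that difference, which leaves the splits a weak test. The highest others gave 561 and 379 and both split the seeds by 3'/5' ratio, while with that ratio as a covariate the count was 90.

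The second pattern is the spread of the seed arrays, of which the main axis held 45.0% of the variance. It may reflect RNA integrity, since it went with the mean log2 3'/5' ratio over the 6 arrays (r = 0.975, exact permutation p = 0.00278, rho 0.943, exact permutation p = 0.0167, 1 relation computed, and r = 0.947 without seed control array 1 and seed helical MWCNT array 2). Medium as the source of that axis is argued against by the control arrays alone, which spanned -29.9 to 15.2 and covered part of the helical MWCNT range of -6.57 to 18.8 (exact permutation p = 0.5, the smallest possible being 0.1). The split with 347 calls in seeds is the one by 3'/5' ratio, seed control arrays 1 and 2 with helical MWCNT array 1 against the rest, which points to a structure of the samples.

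The third pattern is a lean of transcripts which fall from seeds to seedlings toward a still lower level in helical MWCNT seedlings. Over the 100 probe sets with the largest such fall, as the mean of both media, the median log2 difference was -0.27 (SE 0.10), against -0.07 for all probe sets. That SE is taken over the probe sets, which are not independent replicates, and does not measure the spread between arrays. Of the 100 probe sets 77 were lower, 20 past the threshold lower and 0 higher by limma, with medians of -0.34, -0.25 and -0.26 on the 3 helical MWCNT arrays. The helical MWCNT seedling arrays also entered the choice of these probe sets, so part of this lean is built in. On regular medium, 50% of the 92 probe sets called lower in helical MWCNT seedlings passed as lower in seedlings than in seeds. That share was 31.7% for the rises and 30.4% for all probe sets. Admixture of RNA like that of day 1 seeds in the control seedlings is argued against, since 18 of the 20 called falls need more of it (median 6.91% of the seed level) than the 1.57% that abundant members allow. A candidate explanation that stays open is fewer transcripts left over from the seed, by lost seed parts or faster development. DREB1 (0.22) and XET4 (0.26), which fell between the stages, lay above 0 in helical MWCNT against control seedlings.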

How the results depend on the processing

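Fits with 1 helical MWCNT array alone or with the 3'/5' ratio as a covariate and the gene list tests without 1 array were chosen after seeing the data. The later gene lists were put together after the gene symbols were seen and before any fold change was computed. A lone array is assumed to vary like the other groups. Of the named genes, 15 of 18 in seeds, 33 of 35 in seedlings and all 22 of the difference between stages kept their direction under every alternative run, and the call was lost somewhere for 16 of the 26 called in seedlings and 14 of the 17 called for the difference. All 22 and 24 of the stage comparisons kept direction and call. Signal over background limits the dim genes. In all, 2463 gene values stayed on their side, 154 lost the call and 20 gained it. The 6 reversed values are MTA in seedlings (-0.0392 with helical MWCNT array 3 alone), Man4 in seedlings (-0.0245 without helical MWCNT array 3, to 0.18), HSP17-6 in seeds (-0.24 with helical MWCNT array 1 alone, -0.0375 with the 3'/5' covariate), HSP21 in seeds (-0.0641 with array weights) and DFR in seeds (-0.10 without helical MWCNT array 1, to 0.22), and the cause was not tested.

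In seeds the count of 0 by limma (747 at an unadjusted p under 0.05) became 5 with a pseudocount of 1, 5 with array weights and 0 to 3 without 1 array (2 without control array 3, 3 without helical MWCNT array 1). In seedlings the 133 became 212 with a pseudocount of 64, 229 with only the 2 groups in the fit, 687 with array weights, and 36 with helical MWCNT array 3 alone, 34 of them among the 133. It was 74 to 149 without 1 array (83 and 82 without control arrays 1 and 2, 74 and 84 without helical MWCNT arrays 1 and 2), and 59 at a log2 difference of at least 1, a subset by construction. The difference between stages had 57, and 230 with array weights, 90 with the 3'/5' covariate, 19 with helical MWCNT seedling array 3 alone, 22 with helical MWCNT seed array 1 alone and 39 to 80 without 1 array. The stage comparisons had 4068 and 4115 at a log2 difference of at least 1, and 6606 to 7017 and 6758 to 6903 without 1 array. The cause was not tested, except that a lone array leaves fewer samples.

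Of the gene lists in seeds, 0 passed by camera in limma (3 at an unadjusted p under 0.05, 0 by fry), 2 of the later lists did, and 0 to 2 without 1 array (2 without control array 2). In seedlings 5 passed, 3 with an estimated correlation, 3 with helical MWCNT array 3 alone and 3 to 7 without 1 array (3 without helical MWCNT array 1). For the difference between stages 3 passed, 1 with an estimated correlation, 0 of the later lists and 2 to 6 without 1 array (2 without seed control array 3, seed helical MWCNT arrays 1 and 2, seedling control array 3 or seedling helical MWCNT array 2, and 6 without seedling helical MWCNT array 3). Between stages 4 lists on regular and 5 on helical MWCNT medium passed, 0 and 0 with an estimated correlation, 16 and 16 by fry, and on helical MWCNT medium 3 with array 3 alone and 3 of the later lists. An estimated correlation lowers such counts by allowing for genes that vary together, and the cause of the others was not tested.

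The replicate numbers do not pair the arrays (residual r of 0.33, -0.00 and 0.03 in seeds and -0.10, -0.18 and -0.27 in seedlings, and between stages 0.28, -0.05 and 0.32 on regular and -0.05, 0.22 and 0.02 on helical MWCNT medium), and not every array correlated best with its own number. With the replicate number as a block, 0 probe sets passed in seeds by limma, 115 in seedlings (107 of them among the 133), 54 for the difference between stages and 7167 and 7203 between stages. Of the named genes, h52, ERF3 and CHI9 in seedlings and TomloxE, APX and CHS2 for the difference did not pass with the block.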

Other observations

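The tests of phosphate genes and of a shared direction in seeds were chosen only after the results were seen. The copper hypothesis was also drawn from seedling results, those of FESOD and SODCP.2, and only its bounds are recorded as set before its test. The 20 gene lists used here were put together after the gene names and before any difference was computed.

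In seedlings, genes of seed maturation and germination lay lower on helical MWCNT medium (camera adjusted p = 0.00255, adjusted p = 0.0669 with an estimated correlation). Of 11 probe sets 3 fell, MAN2, CHI9 and the dehydrin TAS14, and 4 fell when adjusted over the list alone, with LEA14 (-0.34) added. The beta-glucanase GluB was at 3157 ± 159 and 2591 ± 156 (-0.28, adjusted p = 0.541, n = 3), and the list median was -0.31. A wider phenylpropanoid list of 9 also lay lower (median -0.24, camera adjusted p = 0.00424, adjusted p = 0.123 with an estimated correlation), with CHS1, CHS2 and DFR down. THT1-3, a tyramine hydroxycinnamoyl transferase, was at 149 ± 6.90 and 75.0 ± 20.6 (-0.88, adjusted p = 0.0859), while THT7-8 was at 96.2 ± 5.14 and 137 ± 46.1 (0.41, adjusted p = 0.411). Carotenoid and isoprenoid genes had 0 of 19 past by limma, 3 at an unadjusted p under 0.05, and a median of -0.17 (camera adjusted p = 0.0465, and adjusted p = 0.587 with an estimated correlation), with PDS, phytoene desaturase, at 617 ± 82.1 and 473 ± 44.6 (-0.37, adjusted p = 0.339), ISPE at -0.34 and NCED1, of abscisic acid synthesis, at -0.44. With median centring, which moved the median of all probe sets from -0.07 to 0.04, the carotenoid list had an adjusted p of 0.0748. These genes were chosen after their values were seen.

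Other lists lay higher in seedlings, by small amounts. Metallothioneins had a median of 0.20 over 8 probe sets, 0 of them past by limma and 1 (MT2) at an unadjusted p under 0.05 (camera adjusted p = 0.00612, and adjusted p = 0.587 with an estimated correlation), with MT3 at 336 ± 15.6 and 412 ± 17.7 (0.28, n = 3) and LEMT1 at 8059 ± 749 and 9323 ± 1519 (0.20). The photosynthesis apparatus had a median of 0.18 over 9 probe sets, with 0 past by limma and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0365, and adjusted p = 0.607 with an estimated correlation), with PSBO at 9159 ± 331 and 10501 ± 1524. With quantile normalization both calls were lost, at a median of 0.04 (adjusted p = 0.558) and -0.01 (adjusted p = 0.657), and with median centring that of the photosynthesis apparatus was lost too (median 0.29, adjusted p = 0.0558). Ethylene genes had 1 of 50 up, ERF3, and a median of 0.04 (camera adjusted p = 0.00424, and adjusted p = 0.0669 with an estimated correlation). In seeds 0 probe sets of any list passed by limma, and 747 of all had an unadjusted p under 0.05, but heat shock genes (median 0.31 over 8, MTSHP at 783 ± 332 and 1061 ± 222, 0.50) and auxin response genes (median 0.17 over 17) lay higher, both at a camera adjusted p of 0.0280 and an adjusted p of 0.511 with an estimated correlation. The heat shock and auxin response lists fixed in advance did not pass in seeds, as given above. The mean log2 3'/5' ratio was 2.34 ± 0.72 on regular and 2.92 ± 0.46 on helical MWCNT seed arrays, and whether it bears on the 20 later lists was not tested. The other lists had a camera adjusted p of 0.0688 to 0.980 in seedlings and 0.413 to 0.934 in seeds. With quantile normalization 3 of these passed downward in seedlings, antioxidant genes (median -0.11, adjusted p = 0.0207), polyamine, GABA and proline metabolism (-0.18, 0.0207) and sugar metabolism and transport (-0.11, 0.0330). By camera 0 of 20 passed for the difference between stages (0.0912 to 0.514), 6 had an unadjusted camera p under 0.05 and 0 passed by fry. Between stages, photosynthesis (8.15e-07 and 5.21e-07 on regular and helical MWCNT medium), carotenoid synthesis (0.000566 and 0.00189) and metallothioneins (0.0146 and 0.0101) lay higher in seedlings, and each call was lost with an estimated correlation (adjusted p of 0.231, 0.231 and 0.421 on regular and 0.368, 0.368 and 0.498 on helical MWCNT medium).

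A hypothesis on copper came from the iron superoxide dismutase FESOD, at 2278 ± 70.1 and 1388 ± 95.2 in control and helical MWCNT seedlings (-0.71, adjusted p = 0.00263, n = 3, and -0.47 on its other probe set), while the copper/zinc enzyme SODCP.2 rose. More available copper might give this pair of changes and would then raise CCS, the copper chaperone, and SODCC.1, whose mean difference was 0.0862. SODCC.1 was higher by 0.22 (95% interval 0.05 to 0.39, adjusted p = 0.254), at an unadjusted p under 0.05 as the hypothesis asks, which goes with copper. CCS was at -0.05 with an upper 95% bound of 0.14, below the 0.3 recorded for either gene before this test. This argues against copper as the whole source.

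A hypothesis on phosphate came from RNALE, known to be induced by phosphate starvation and lower in helical MWCNT seedlings. A better phosphate supply could lower such genes together, and the median over PT1, PT2, TPSI1, rnalx, psi14A and psi14B was -0.28, with 2 of them, rnalx (-0.49, adjusted p = 0.154) and PT2 (-0.37, adjusted p = 0.382), lower at an unadjusted p under 0.05. PT1 was at -0.27 and TPSI1 at 0.12, and PT2, psi14A and psi14B were near the floor, so the question stays open.

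A last hypothesis was that seeds on day 1 respond in the same direction as seedlings, only less. Of the 133 seedling calls, 64 had the same direction in seeds (48.1%), where the highest of the other splits of the seed arrays gave 55.6%. The 10 splits are too few to settle it.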
